A study of Mus musculus with 8 samples.

How the data were processed

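RNA from mouse liver was sequenced in 3 control and 5 knockout samples. Per the labels' protocols, frozen tissue was lysed in Trizol, the RNA was treated with DNase, and libraries were made with a stranded total RNA kit after depletion of ribosomal RNA. Controls are labelled as wild type. Knockout animals carried the Alb-cre transgene, which expresses Cre recombinase in hepatocytes, together with targeted alleles of both mitoferrin genes.

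Per the submitters' processing notes, reads were processed with Novoalign 2.8, the mouse build mm10 and DESeq2. The program that counted reads per gene, and whether it used the strand of each read, are not given in the sources used here. The table deposited by the authors lists 15864 genes with Ensembl identifiers, and 138 of them carry no symbol. Its raw read counts per gene are whole numbers, and the sparsest gene holds 16 counts over the 8 libraries and 10 in its best library. Genes with fewer counts were therefore not analysed here, and 1 emptied line of the table was left out. Per the file headers, the table also holds regularised log2 values and FPKM values made by the authors, neither of which entered a test. The authors' own log2 fold change and a score for its adjusted p stand in the same table. That deposited score lies on a -10 log10 scale: its rank correlation with the same transform of the adjusted p from a DESeq2 fit of the counts was 0.992 across genes, with a median ratio of 0.983. Positions are given in mm10, counted from 1. The starts in the table count from 0, since 11363 of the 15626 identifiers found in GENCODE M21 start 1 base before the annotated start.

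Library totals were 43.1, 42.3 and 35.5 M counts in control replicates 1 to 3 and 29.0, 29.4, 26.1, 24.6 and 31.9 M (M, mega) in knockout replicates 1 to 5. After scaling, 1 count stood for 0.0227 to 0.0404 CPM. Intervals for genes with few counts cover counting error only, because reads without molecular identifiers are not independent molecules. All 8 libraries were kept as separate samples, as labelled. A chi-square statistic of counts between replicates of a group was 30.8 to 86.1 per gene, above sampling noise, which argues against repeated sequencing of the same library and does not show that the samples are separate animals.

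The tests were run in R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16 at its defaults (min.count 10, min.total.count 15), which kept 14664 genes. Counts were scaled by TMM factors. Knockout was compared with control by edgeR's quasi-likelihood test, with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every edgeR adjusted p comes from this test, which is two-sided. A standard error is the fold change divided by the root of its F statistic. CPM values are normalised by the TMM-scaled library size, and log2 CPM used a prior count of 2. The common biological coefficient of variation was 0.191. DESeq2 1.42.0 and limma-voom from limma 3.58.1 were run as alternatives. Figures were drawn with matplotlib 3.10.9.

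Before the data were examined, 41 gene lists were fixed for pathways of iron, heme, mitochondria, stress, growth and liver metabolism and for markers of liver cell types, sex and time of day. 40 lists had at least 3 tested members. Each was tested with camera in limma at the preset correlation of 0.01, which compares the members with all other genes, and p-values were adjusted over the 40 lists. Camera was repeated with a correlation estimated from the data, and fry was run as a test of whether the members move, on balance, in 1 direction. The score of a list is the mean over its members of log2 CPM, each centred on its mean over the 8 libraries. Scores and deleted genes were also compared by exact two-sided permutation over the 56 splits of 8 samples into 3 and 5, for which the smallest p is 0.0179. Member counts are given over all genes and adjusted over the list alone.

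Named genes were chosen by a rule fixed before the data were examined. It took the deleted genes and 14 further key genes. It also took up to 10 genes per direction with the greatest fold change among those that passed, with an average log2 CPM of at least 3 and no overlap of the groups, leaving out predicted genes, Xist and Y-linked genes. From each list it took the 2 members with the smallest p in each direction that passed or, where none passed, the member with the smallest p. Other genes named here lie outside this rule and were chosen after their values were seen. Some are marked so where they appear. Without a mark are Sult2a1, Sult2a2, Cyp2a4, Cyp17a1, Cyp3a16, Cyp3a41a, Cyp2b13, Cyp2d9, Hsd3b5, Slc39a14, Por, Lect2, Xist and the clock genes.

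The procedures were tested on simulated counts of 14509 genes with 3 and 5 libraries. EdgeR recovered 74% of genes changed by a log2 fold of 1 and 100% of those changed by 2, with 3.87% false calls. DESeq2 recovered 84% and 100% with 14.8% false calls, and limma-voom 74% and 100% with 3.33%. Camera called 0 of 40 random lists and the planted list. The simulated genes were drawn independently, so this does not test camera where genes of a list vary together. In the real lists the estimated correlation reached 0.797, for Ppara targets. The statistic for genes lying close together gave a permutation p of 0.600 for random genes and 0.000999 for planted neighbours.

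Alternatives covered other tests and size factors, filters and thresholds, the replicate number as a block, each library left out in turn, and a split by the numbers in the sample titles. All control samples and knockout replicates 4 and 5 have numbers that begin with 82, and knockout replicates 1 to 3 have numbers that begin with 85. What these series stand for is not stated, and the series 85 holds knockout samples only. 4 kinds of alternative were added after seeing the data: leaving out knockout replicates 1 and 2, thinning every library to the smallest total, removing a trend with gene length, and testing the iron list without the deleted genes. Leaving out knockout replicate 3 beside 1 and 2 was also run, and is the same fit as that of the samples numbered 82.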

Results

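Mitoferrin 1 and mitoferrin 2, encoded by Slc25a37 and Slc25a28, are carriers that bring iron across the inner mitochondrial membrane for the synthesis of heme and iron-sulfur clusters. Liver RNA was profiled in chow-fed mice with Alb-cre and targeted alleles of both carrier genes, and in wild-type controls of similar age. The comparison asks which liver transcripts differ when hepatocytes lose both mitoferrins, within a study that the submitters titled as one of liver regeneration and cell proliferation. Only the knockouts are described as carrying Alb-cre, so the comparison does not separate presence of the transgene from loss of the carriers. The data are read counts per gene for 3 control and 5 knockout livers. Control libraries held 35.5 to 43.1 M counts and knockout libraries 24.6 to 31.9 M, so each control library was deeper than each knockout library. The labels call the samples replicates without saying that each came from a separate animal, so the p-values measure the spread between these samples. In a principal component analysis, the component with 27.8% of the variance placed the controls between -30.7 and -17.1 and the knockouts between -5.90 and 30.5, and the next component held 18.0%.

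Slc25a28 transcripts were almost lost from every knockout liver. Slc25a28 (ENSMUSG00000040414, minus strand of chromosome 19, 43663822 to 43674881) was counted at 18.1, 16.6 and 16.6 CPM in control replicates 1 to 3 and at 0.753, 0.731, 0.592, 0.888 and 0.662 CPM in knockout replicates 1 to 5. Its mean fell from 17.1 ± 0.851 CPM (SD, n = 3) to 0.725 ± 0.111 CPM (SD, n = 5), which left 4.24% of the control level, with a log2 fold change of -4.56 ± 0.128 (SE, edgeR adjusted p = 1.92e-07). Slc25a37 (ENSMUSG00000034248, minus strand of chromosome 14, 69241848 to 69285112) was counted at 17.4, 12.9 and 23.0 CPM in the controls and at 10.6, 8.74, 5.76, 8.15 and 8.35 CPM in the knockouts. All 5 knockout livers lay below all 3 controls, with means of 8.31 ± 1.72 and 17.8 ± 5.06 CPM (SD, n = 5 and 3) and 46.8% of the control level remaining. The log2 fold change of Slc25a37 was -1.09 ± 0.209 (SE). It did not pass over all genes by edgeR (adjusted p = 0.104), passed by DESeq2 (adjusted p = 0.000347), and gave p = 0.0179 by exact permutation, the smallest that this design allows. Its edgeR adjusted p lay between 0.0841 and 0.247 when single libraries were left out. Alb-cre acts in hepatocytes, and the share of the remaining counts that came from other liver cells was not measured. Which exons the targeted alleles lack was not used here either. The whole-gene count is therefore a limited check of the Slc25a37 label.

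**Figure D1:**
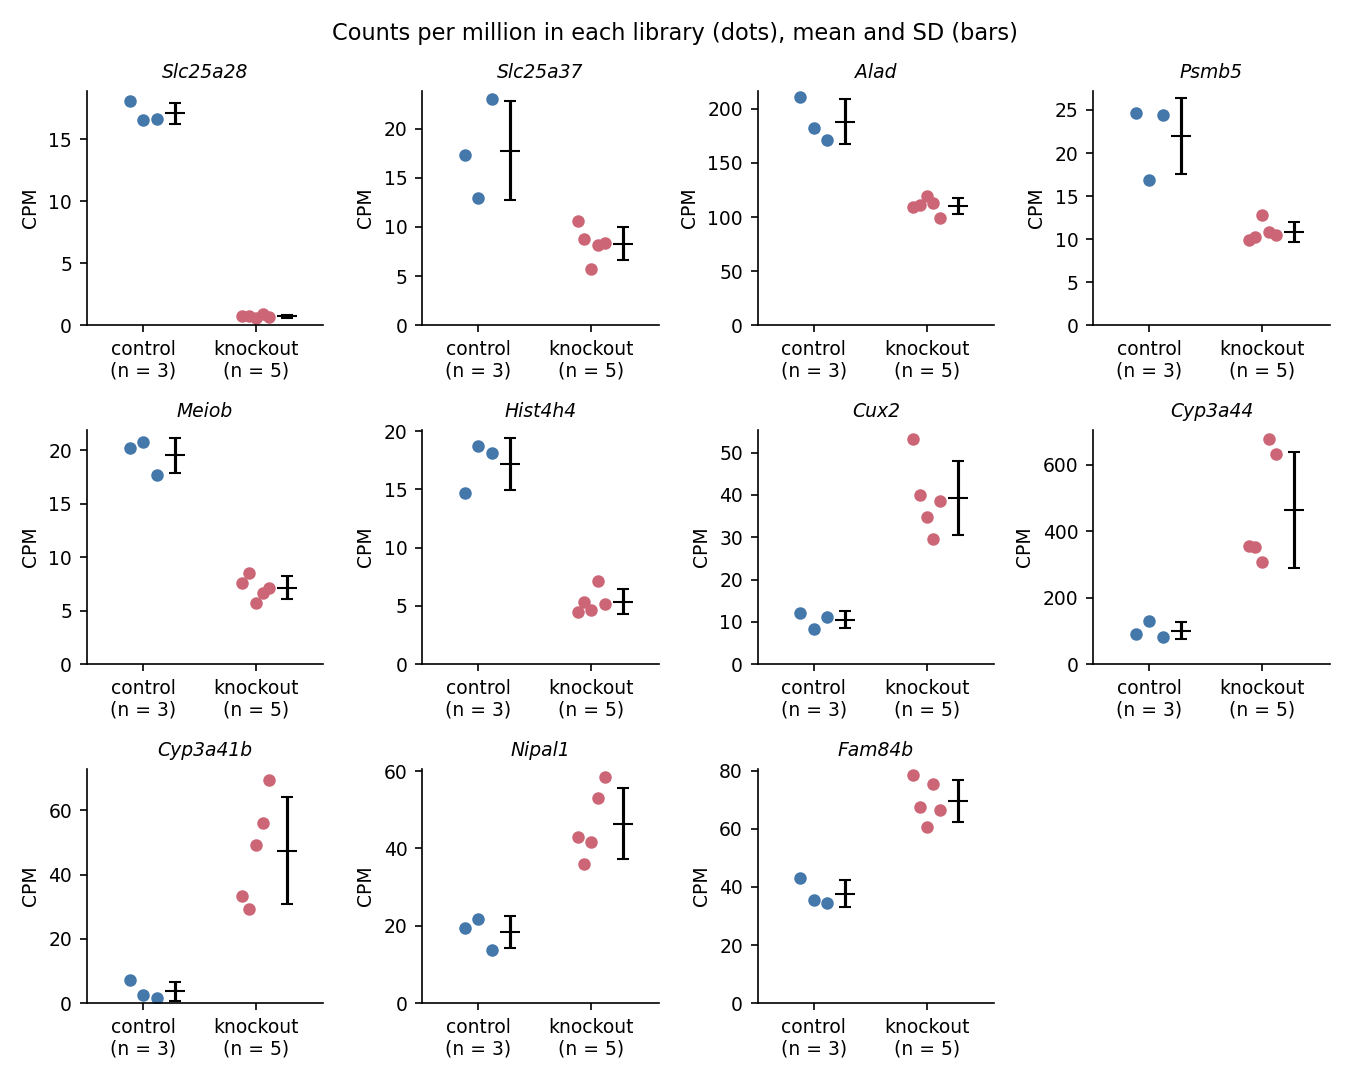
CPM (linear axis) of 11 genes in control (blue, n = 3) and knockout (red, n = 5) livers, with each dot a library and bars giving the mean and SD. In every panel the groups do not overlap, which the rule for naming genes required of all but Slc25a28 and Slc25a37. Slc25a28 lies between 0.592 and 0.888 CPM in the knockouts.

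Beyond the deleted genes, knockout livers differed from controls in few transcripts. Among them were an enzyme of heme synthesis and 2 members of the list of genes that female mouse livers express more strongly than male ones. Alad, which encodes delta-aminolevulinate dehydratase (ENSMUSG00000028393, chromosome 4, 62509169 to 62519918), fell from 188 ± 20.8 to 111 ± 7.45 CPM (SD, n = 3 and 5), a log2 fold change of -0.77 ± 0.0970 (SE, edgeR adjusted p = 0.0252). That call held in 1 of 8 fits with a library left out. It was lost with knockout samples numbered 82 alone or 85 alone (edgeR adjusted p = 0.134 and 0.086). Cux2, a transcription factor of female liver (ENSMUSG00000042589, chromosome 5, 121858387 to 122050102), rose from 10.6 ± 1.96 to 39.3 ± 8.79 CPM, a log2 fold change of 1.90 ± 0.199 (SE, edgeR adjusted p = 0.00556). In all, 16 of 14664 tested genes passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 7 higher and 9 lower in knockout.

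Among the other higher genes, the cytochrome P450 genes Cyp3a44 and Cyp3a41b rose by log2 fold changes of 2.21 ± 0.317 and 3.65 ± 0.507 (SE, edgeR adjusted p = 0.0414 and 0.0353), from 101 ± 25.9 to 464 ± 175 CPM and from 3.72 ± 2.97 to 47.4 ± 16.6 CPM. These Cyp3a genes are close paralogs, and the share of reads that belongs to each copy is uncertain. Nipal1, of a family of magnesium transporters, rose from 18.4 to 46.4 CPM and Fam84b from 37.7 to 69.6 CPM (edgeR adjusted p = 0.0414 and 0.0265). Enpp6, a choline-specific phosphodiesterase named after its values were seen, rose from 1.15 ± 0.0682 to 5.11 ± 0.818 CPM, a log2 fold change of 2.15 ± 0.174 (SE, edgeR adjusted p = 0.00142).

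Among the lower genes, Psmb5, a catalytic subunit of the proteasome, fell from 22.0 ± 4.46 to 10.8 ± 1.13 CPM (edgeR adjusted p = 0.0353). Mir686, which lies inside Psmb5 on the same strand, fell with a log2 fold change of -1.08 (edgeR adjusted p = 0.0270). In control replicates 1 to 3 it was at 9.01, 6.27 and 8.71 CPM, where Psmb5 was at 24.7, 16.8 and 24.4 CPM. In the knockouts it was at 3.39 to 4.00 CPM against 9.855 to 12.7 CPM. Whether reads were counted in both is not known, so the 2 calls are not taken as independent. Meiob, a gene of meiotic recombination, fell from 19.5 ± 1.64 to 7.13 ± 1.07 CPM with a log2 fold change of -1.45 ± 0.130 (SE, edgeR adjusted p = 0.00218). The histone gene Hist4h4, 1 of several histone H4 copies with similar sequence, fell from 17.2 ± 2.21 to 5.37 ± 1.07 CPM with a log2 fold change of -1.68 ± 0.157 (SE, edgeR adjusted p = 0.00235). Cebpe, a transcription factor of granulocytes, was nearly absent from knockout liver, with 1 count in all knockout libraries against 501 in the controls. After scaling for depth this was 0.171% of the control level, with a 95% counting interval from 0.00432% to 0.956% (edgeR adjusted p = 0.000119). Gm9825 had 8 counts against 181 (3.78% of control, 95% counting interval 1.61% to 7.61%, edgeR adjusted p = 0.00218), and ENSMUSG00000048149, which has no symbol, had 27 against 223 (10.4%, 6.68% to 15.5%, edgeR adjusted p = 0.00192). Cebpe, Gm9825, ENSMUSG00000048149 and Mir686 were named after their values were seen. Cebpe, Psmb5 and Mir686 lie on chromosome 14 within 20 Mb of Slc25a37. Alad, Hist4h4 and Meiob lie in 5 Mb windows of chromosomes 4, 6 and 17 that hold 5, 6 and 4 of the 100 genes with the smallest p.

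The count of 16 genes compares with 1517 genes at an unadjusted p under 0.05, of which 832 were higher and 685 lower, where 733.2 would be expected by chance. That expectation has no spread here, because genes vary together and the count was not taken over other splits. The excess is therefore not a test of genotype. DESeq2 placed 146 genes higher and 98 lower, and the authors' deposited table holds 131 higher and 104 lower at the same threshold. All 16 genes were among the calls of both. Leaving out control replicate 1, 2 or 3 gave 24, 20 or 8 genes, and leaving out knockout replicate 1, 2, 3, 4 or 5 gave 8, 9, 30, 14 or 9. Slc25a28, Cebpe, Enpp6, Meiob, Hist4h4, Cux2, Gm9825 and ENSMUSG00000048149 were called each time. The other 8 genes were lost in 6 or 7 of the 8 omissions, with edgeR adjusted p of up to 0.0855 for Alad (called only without knockout replicate 3), 0.130 for Cyp3a41b, 0.136 for Cyp3a44, 0.0983 for Nipal1, 0.101 for Fam84b, 0.128 for Psmb5 and 0.103 for Mir686. Nipal1 was kept only without knockout replicate 2 or 3, Fam84b and Cyp3a41b without control replicate 1 or knockout replicate 3, Psmb5 and Mir686 without control replicate 2 or knockout replicate 3, and Cyp3a44 only without knockout replicate 3. Among the samples numbered 82 alone, with 3 controls and 2 knockouts, 13 genes were higher and 11 lower, and 8 of these 24 were among the 16. In the samples numbered 82 the log2 fold change was -0.82 for Alad and -1.48 for Hist4h4, neither of which passed (edgeR adjusted p = 0.134 and 0.0713), while Slc25a28, Cux2 and Meiob passed (edgeR adjusted p = 0.00117, 0.0445 and 0.0215).

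Genes of female-biased liver expression rose as a group, which was the most pronounced list difference. Of 13 members, 11 had a positive fold change, with a median log2 fold change of 1.25, and the score of the list was higher in all 5 knockout livers than in the controls, at 0.446 ± 0.268 against -0.744 ± 0.344 (SD, n = 5 and 3). Over all genes, 2 members rose, among them Cux2. Adjusted over the list alone, 8 rose and 1 fell. Those that rose over the list alone included the steroid sulfotransferases Sult2a1 and Sult2a2, with log2 fold changes of 3.72 ± 0.725 and 1.59 ± 0.622 (SE), and Cyp2a4, Cyp17a1, Cyp3a16 and Cyp3a41a, at 1.49, 1.41, 2.88 and 0.94. Of these, Cyp17a1 lies within 20 Mb of Slc25a28 on chromosome 19. Cyp2b13 fell, with a log2 fold change of -1.68 ± 0.409 (SE). The list passed (camera adjusted p = 1.43e-07), with adjusted p = 0.118 with an estimated correlation, and fry gave an adjusted p of 0.00878. Exact permutation of the scores gave p = 0.0179, or 0.357 adjusted over the lists. Among the samples numbered 82 the list was also higher (camera adjusted p = 0.000524).

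Male-biased genes did not pass as a group, with 8 of 11 members lower (camera adjusted p = 0.0965). Over all genes none of them passed edgeR, and adjusted over the list alone 2 fell, the fatty acid elongase Elovl3, from 16.7 ± 4.11 to 5.88 ± 2.14 CPM, and Cyp2d9, from 34.8 ± 6.96 to 12.7 ± 4.63 CPM. Elovl3 lies on chromosome 19 within 20 Mb of Slc25a28. Hsd3b5 lay the other way, with a log2 fold change of 1.91 ± 0.697 (SE) that did not pass (edgeR adjusted p = 0.398). Xist was present in every library, at 517 to 1432 CPM.

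**Figure D2:**
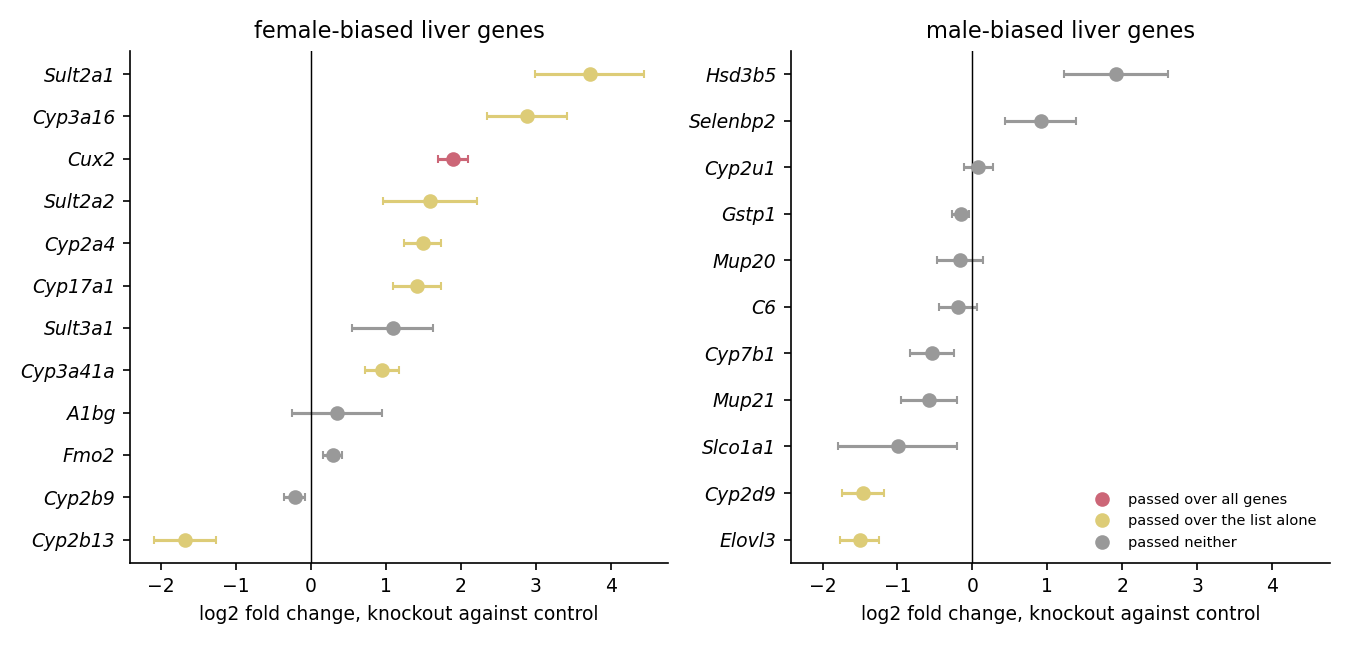
Log2 fold change of knockout (n = 5) against control (n = 3) for 12 genes of the female-biased list and 11 of the male-biased list, with bars of 1 SE. Red points passed over all genes, yellow points passed when adjusted over the list alone, and grey points passed neither.

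Genes of iron handling and heme showed few differences beyond the carriers and Alad. Among 8 heme synthesis enzymes Alad alone passed, over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.154). The log2 fold changes of Alas1, the rate-limiting enzyme of the pathway, and of Fech, the ferrochelatase, were 0.31 ± 0.349 and 0.00 ± 0.0838 (SE, edgeR adjusted p = 0.794 and 0.991). Of 26 genes for iron uptake, storage and regulation, Slc25a28 fell over all genes. Adjusted over the list alone, Slc25a28 and Slc25a37 fell and the metal transporter Slc39a14, which lies within 20 Mb of Slc25a37 on chromosome 14, rose from 168 ± 12.8 to 218 ± 18.6 CPM. This list did not pass by camera (adjusted p = 0.160). Its adjusted p of 0.00878 by fry rested on the deleted genes, since it was 0.742 for the 24 members without them (camera adjusted p = 0.648). The transferrin receptor Tfrc, hepcidin (Hamp) and the ferritin genes Fth1 and Ftl1 did not pass, with log2 fold changes of 0.60 ± 0.406, -0.44 ± 0.280, 0.12 ± 0.107 and -0.07 ± 0.105 (SE, edgeR adjusted p from 0.619 to 0.856). Genes of iron-sulfur cluster assembly had 22 of 27 members lower, a median log2 fold change of -0.06 and no member that passed (camera adjusted p = 0.129). Heme breakdown and transport did not pass either (camera adjusted p = 0.228). Hmox1, the inducible heme oxygenase, was at 19.9 ± 3.64 CPM in control and 20.1 ± 5.71 CPM in knockout (SD, n = 3 and 5, edgeR adjusted p = 0.992).

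Nuclear genes of the respiratory chain were slightly lower in knockout by camera, though not in every knockout liver: knockout replicate 3 scored 0.198 for complex I and 0.196 for complexes II to IV, above the highest control at 0.114 and 0.124. Complex I genes had 32 of 36 members lower, with a median log2 fold change of -0.12, and passed (camera adjusted p = 0.00462, adjusted p = 0.836 with an estimated correlation). Ndufs4 had the smallest p, with 69.1 ± 2.66 CPM in control and 56.3 ± 4.16 CPM in knockout (edgeR adjusted p = 0.256). Complexes II to IV had 24 of 27 members lower, with a median of -0.09 (camera adjusted p = 0.0298, adjusted p = 0.836 with an estimated correlation). By fry the adjusted p was 0.571 and 0.610, and by exact permutation of the scores p was 0.286 and 0.339. No member of either list passed by edgeR, over all genes or adjusted over the list alone. The ATP synthase genes were lower in 14 of 14 members without passing (camera adjusted p = 0.0965), and knockout replicate 3 again scored above every control (0.243 against 0.151). Mitochondrially encoded mRNAs lay the other way, with 5 of 8 members higher and a median of 0.41, and did not pass (camera adjusted p = 0.0572). The log2 fold change across genes rose with gene length (Spearman's rho 0.219, across genes, which are not independent replicates). Length was also correlated with the deviation of log2 CPM in each library from the mean of the 8 libraries. Spearman's rho was 0.169, 0.217 and 0.213 in knockout replicates 1, 2 and 5 and between -0.261 and -0.0414 in the other 5 libraries. These values are relative to that mean and do not give the trend of expression itself. Once the trend with length was removed, the camera adjusted p was 0.176 for complex I and 0.376 for complexes II to IV. Neither list passed without knockout replicates 1 and 2, whose clock genes stand apart (camera adjusted p = 0.444 and 0.594). Complex I was not called without control replicate 1 or knockout replicate 1 (camera adjusted p = 0.0702 and 0.0831). Complexes II to IV were not called without control replicate 1 or 3 or knockout replicate 1, 2 or 5 (camera adjusted p = 0.206, 0.0654, 0.138, 0.161 and 0.0919), nor with every library thinned to the smallest total (0.0571).

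The other mitochondrial lists did not pass with all 8 libraries. Mitochondrial chaperones and proteases (camera adjusted p = 0.242), tricarboxylic acid cycle enzymes (0.601) and genes of mitochondrial biogenesis (0.601) had no member that passed. In the last 2 lists the median and the mean differed in sign, at 0.02 and -0.01 for the cycle, which camera placed lower, and at -0.03 and 0.06 for biogenesis, which camera placed higher. Targets of Atf4 in the integrated stress response had 13 of 23 members lower (camera adjusted p = 0.256). The stress hormones Fgf21 and Gdf15 had log2 fold changes of 0.74 ± 0.766 and -0.44 ± 0.324 (SE, edgeR adjusted p = 0.769 and 0.677).

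Genes of the urea cycle and amino acid breakdown were lower in 19 of 20 members, with a median log2 fold change of -0.30 (camera adjusted p = 0.00019, adjusted p = 0.731 with an estimated correlation). The groups overlapped, with control replicate 3 at a score of -0.114 and knockout replicate 5 at 0.121, and neither fry (adjusted p = 0.491) nor exact permutation of the scores (p = 0.161) passed. No member passed by edgeR, over all genes or adjusted over the list alone. Tdo2, which opens tryptophan breakdown, had a log2 fold change of -0.44 ± 0.138 (SE, edgeR adjusted p = 0.321). Drug-metabolising P450 genes were lower in 23 of 30 members (camera adjusted p = 0.0156, adjusted p = 0.231 with an estimated correlation, fry adjusted p = 0.0466, exact permutation p = 0.143). None of these passed over all genes, and adjusted over the list alone Cyp2c50, Cyp2d9 and Cyp2b13 fell and Por, Cyp3a16 and Cyp3a41a rose. Cyp2c50, which lies within 20 Mb of Slc25a28 on chromosome 19, was at 821 ± 124 CPM in control and 447 ± 56.2 CPM in knockout. This list was not called without control replicate 3 (camera adjusted p = 0.0654) or with the length trend removed (0.0858). Nrf2 targets, genes of the antioxidant response, were lower in 17 of 22 members with none that passed (camera adjusted p = 0.0156, adjusted p = 0.731 with an estimated correlation, fry adjusted p = 0.338, exact permutation p = 0.0536), and were not called without control replicate 1 or knockout replicate 4 (0.116 and 0.0610). Nqo1, a classical Nrf2 target, had a log2 fold change of -0.49 ± 0.149 (SE, edgeR adjusted p = 0.307).

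In all, 1 list was higher and 5 were lower by camera. With an estimated correlation 0 lists passed, against 3 at an unadjusted p under 0.05, and fry called 1 higher and 2 lower. With the deleted genes taken out of the iron list, fry called 1 higher and 0 lower, against 3 lower at an unadjusted p under 0.05, and the P450 list had a fry adjusted p of 0.0699. Of the 56 splits of the 8 samples into 3 and 5, 50 gave at least 6 called lists, so the number of calls is no more than unrelated splits give. Among the samples numbered 82, 2 lists were higher and 12 lower, with camera adjusted p of 0.000524 for complex I, 0.0139 for complexes II to IV, 0.0167 for Nrf2 targets, 0.0172 for P450 genes and 0.0351 for the urea cycle list. Lists called there and not with all 8 libraries were heme synthesis (0.0237), iron-sulfur cluster assembly, ATP synthase, the tricarboxylic acid cycle and bile acid and organic anion transport (0.0139 each), mitochondrial chaperones and proteases (0.0483) and cholesterol synthesis (3.54e-06), lower, and mitochondrially encoded mRNAs, higher (0.0294). With the knockout samples numbered 85 against all controls, which are numbered 82, the calls of complex I, complexes II to IV and Nrf2 targets were lost (camera adjusted p = 0.0531, 0.117 and 0.0531), while the urea cycle list, P450 genes and the female-biased list kept theirs (3.77e-05, 0.0108 and 5e-06), and p53 targets, lower (0.0244), and fatty acid synthesis and Ppara targets, higher (0.00740 and 0.00287), were gained. With the replicate number as a block complex I and complexes II to IV were lost (0.0608 and 0.138), while p53 targets and periportal genes, lower (0.00780 and 0.00980), and fatty acid synthesis and Ppara targets, higher (0.00166 and 2.43e-05), were gained.

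Lists of proliferation and growth did not pass with all 8 libraries. The cell cycle list had 15 of 26 members lower (camera adjusted p = 0.363) with none that passed by edgeR, but was called lower without control replicate 3 (camera adjusted p = 0.0172). Mki67, a marker of cycling cells, was at 3.38 ± 0.947 CPM in control and 4.91 ± 2.17 CPM in knockout (edgeR adjusted p = 0.618). Targets of p53 were lower in 14 of 18 members (camera adjusted p = 0.183) and were called lower with the knockout samples numbered 85 (0.0244). Cdkn1a, which encodes p21, had a log2 fold change of -0.23 ± 0.737 (SE, edgeR adjusted p = 0.943). Among fetal liver and growth genes (camera adjusted p = 0.601), H19 rose when adjusted over the list alone, from 0.313 ± 0.0987 to 0.948 ± 0.362 CPM, while Afp did not pass (edgeR adjusted p = 0.666). Antioxidant and ferroptosis genes did not pass (camera adjusted p = 0.639), and the median and mean of that list differed in sign, at -0.03 and 0.22. Its member Mt2, a metallothionein, rose when adjusted over the list alone, from 1.62 ± 0.222 to 15.2 ± 14.4 CPM, and was highest in knockout replicate 4 at 39.7 CPM.

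Lists of lipid, bile acid and glucose metabolism did not pass with all 8 libraries either. Camera adjusted p was 0.154 for fatty acid and triglyceride synthesis, cholesterol synthesis, and fatty acid oxidation with Ppara targets, 0.0767 for bile acid synthesis, 0.201 for bile acid and organic anion transport, and 0.648 for gluconeogenesis and glycolysis. Pnpla3, a lipid droplet protein, rose when adjusted over the synthesis list alone, from 19.8 ± 4.03 to 47.7 ± 14.5 CPM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of 0.55 ± 0.578 (SE, edgeR adjusted p = 0.777). Periportal and pericentral hepatocyte genes did not pass (camera adjusted p = 0.195 for both), and adjusted over the list alone the pericentral genes Tbx3 rose, from 18.4 ± 1.59 to 33.8 ± 6.13 CPM, and Lect2 fell, from 205 ± 4.36 to 160 ± 16.6 CPM.

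Markers of the cell types of liver did not pass as lists with all 8 libraries. Camera adjusted p was 0.425 for secreted proteins of hepatocytes, 0.291 for cholangiocyte markers, 0.280 for stellate cell and fibrosis genes, 0.601 for Kupffer cell markers, 0.418 for monocyte and neutrophil markers, 0.515 for lymphocyte markers, 0.956 for endothelial markers and 0.463 for erythroid markers. Adjusted over the list alone, the collagen gene Col5a2 fell from 15.3 ± 9.17 to 6.09 ± 1.27 CPM and the neutrophil gene S100a9 from 4.20 ± 2.52 to 1.39 ± 0.588 CPM. Acute-phase genes (0.601), immediate early and heat shock genes (0.601) and the circadian clock list (0.242) did not pass. Median and mean log2 fold change differed in sign for monocyte and neutrophil markers (0.03 and -0.34), erythroid markers (-0.32 and 0.13), endothelial markers (-0.05 and 0.04) and acute-phase genes (0.01 and -0.07). The clock list differed within the knockout group. Dbp, an output gene of the clock, was at 69.3 and 54.4 CPM in knockout replicates 1 and 2 and at 1.23 to 2.93 CPM in the other 6 livers, and Arntl, which encodes the clock activator Bmal1, was at 13.2 and 7.21 CPM against 36.98 to 43.6 CPM. Without these 2 samples 3 genes were higher and 8 lower, and 8 of these 11 were among the 16, while 2 lists were higher and 5 lower. These included 3 lists not called with all 8 libraries, cholesterol synthesis (camera adjusted p = 2.17e-08) and male-biased genes (0.0185), lower, and Ppara targets, higher (0.0410). With the length trend removed mitochondrially encoded mRNAs were called higher (0.0433).

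Several lists that did not pass with all 8 libraries were called when 1 was left out. By camera adjusted p these were cholesterol synthesis (0.0274) and male-biased genes (0.0109), both lower, without control replicate 1. Without control replicate 2 they were bile acid synthesis, lower (0.0278), and acute-phase genes, higher (0.00475). Without control replicate 3, beside the cell cycle list, lymphocyte markers were lower (0.0179) and mitochondrially encoded mRNAs (0.000415) and Ppara targets (0.0268) higher. Leaving out knockout replicate 2 gave cholesterol synthesis (2.19e-06) and male-biased genes (0.0415), lower, and mitochondrially encoded mRNAs, higher (0.0453). Leaving out knockout replicate 3 gave heme synthesis (0.0398), iron-sulfur cluster assembly (0.0143), ATP synthase (0.000105), mitochondrial chaperones and proteases (0.0184) and bile acid synthesis (0.0452), lower, and mitochondrially encoded mRNAs, higher (0.0143). Fatty acid and triglyceride synthesis was higher (0.0117) and male-biased genes lower (0.0392) without knockout replicate 4, and Ppara targets were higher (0.0380) without knockout replicate 5.

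**Figure D3:**
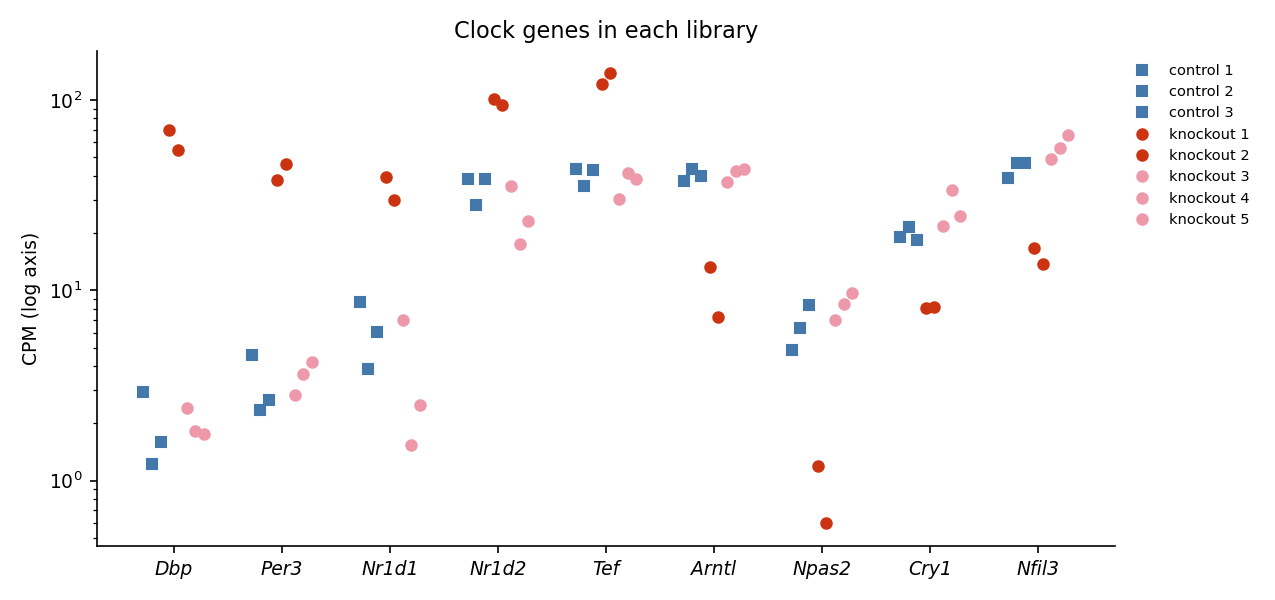
CPM (log axis) of 9 clock genes in each library, with blue squares for control, dark red circles for knockout replicates 1 and 2 and pink circles for knockout replicates 3 to 5. Knockout replicates 1 and 2 lie apart from the other 6 libraries for all 9 genes.

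**Figure D4:**
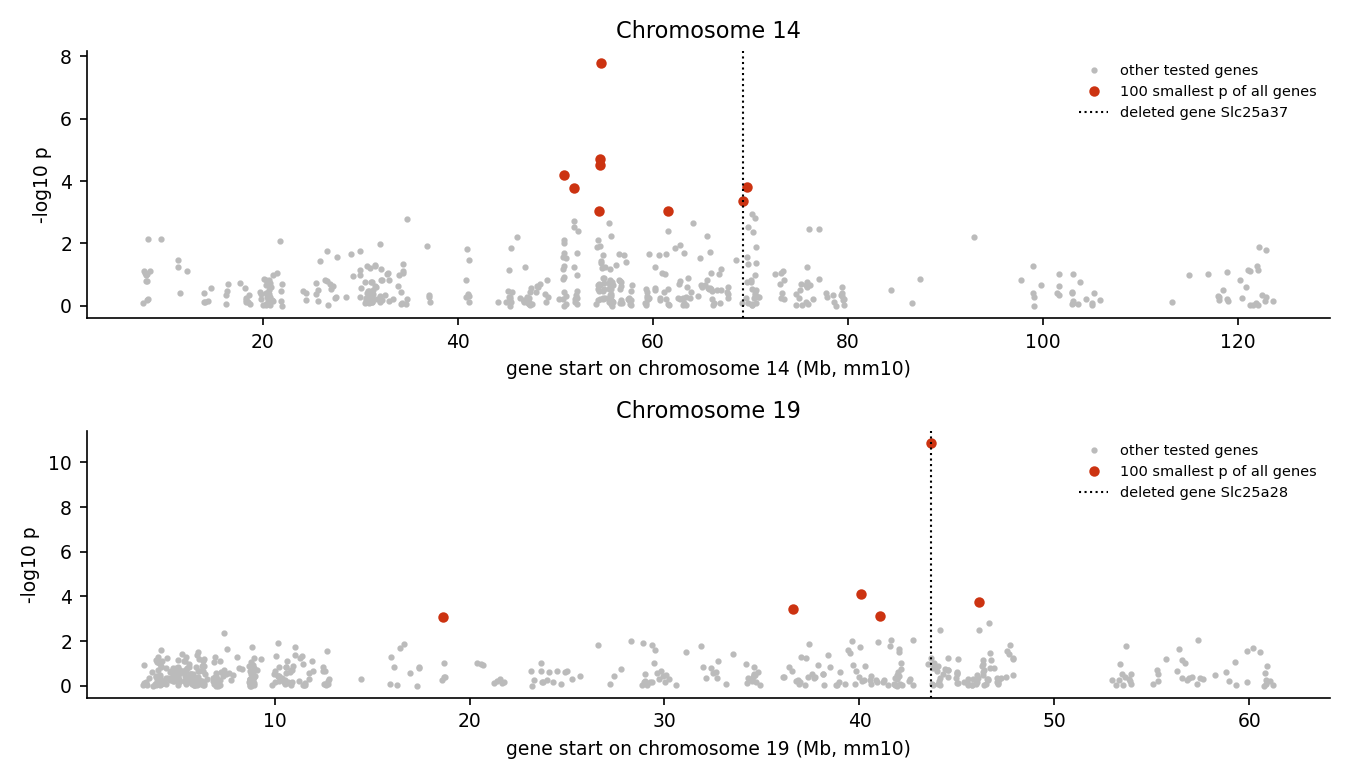
The -log10 of the unadjusted edgeR p of each tested gene against its start on chromosomes 14 and 19 (Mb, mm10), with the 100 smallest p of all genes in red and a dotted line at the deleted gene. Red points include Cebpe, Psmb5 and Mir686 between 54 and 55 Mb on chromosome 14.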

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

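No test in this part was chosen after its result was seen: the gap of the highest or lowest knockout sample to its neighbour, divided by the range of the 5 samples, was compared with Dixon's critical value of 0.71, and the 3 controls were not tested. Of 110 genes, list scores and library measures examined, 9 exceeded it, where chance exceeds it in about 1 of 20. The items are not independent, since lists share members with the named genes, and some genes were named after their values were seen.

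Hepcidin (Hamp) was low in knockout replicate 3, at 185 CPM against 382 to 464 CPM in the other 4, a ratio of 0.789. The ferritin gene Ftl1 was low in knockout replicate 2, at 468 CPM against 563 to 606 CPM (0.715). The stress hormone gene Gdf15 was low in the same sample, at 2.62 CPM against 5.57 to 7.25 CPM (0.738). H19, an imprinted RNA of fetal liver, was low in knockout replicate 4, at 0.363 CPM against 0.908 to 1.26 CPM (0.726). Cebpe gave a ratio of 1 because its single knockout count lay in knockout replicate 2. Targets of Ppara and genes of fatty acid oxidation had a list score of 0.962 in knockout replicate 3 against -0.193 to -0.0703 in the others (0.893). The score of Atf4 targets was also highest in knockout replicate 3, at 0.184 against -0.139 to -0.0644 (0.769). Kupffer cell markers scored highest in knockout replicate 4, at 0.492 against -0.179 to -0.000187 (0.734). Monocyte and neutrophil markers scored lowest in knockout replicate 5, at -0.560 against -0.0646 to 0.115 (0.735).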

How the results depend on the processing

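Tests chosen after seeing the data are those without knockout replicates 1 and 2, with thinned libraries, with the length trend removed and with the iron list without the deleted genes. Other size factors, filters on low counts and limma-voom gave 7 or 8 genes higher and 9 or 10 lower, and the same 16 genes were among them. An alternative for tables without counts was not run. At 24.6 to 43.1 M counts, a fold change of a gene with few counts, such as Cebpe, is limited by depth. The cause of each change given here was not tested, except that fewer samples enter a fit without a library.

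DESeq2 gave 146 genes higher and 98 lower and called Slc25a37 (-1.09). An adjusted p under 0.01, or a test against a 1.5-fold change, left 2 higher. Camera with an estimated correlation gave 0 lists higher and 0 lower, and fry 2 lower. Samples numbered 82 gave 13 genes higher, and 2 lists higher and 12 lower. Knockout samples numbered 85 against all controls, which are numbered 82, gave 3 lists higher and 3 lower. Without knockout replicates 1 and 2, 3 genes and 2 lists were higher, and leaving out knockout replicate 3 as well left the samples numbered 82, so that this is the same fit, with the same 13 genes higher. Removing the length trend left 2 lists higher and 2 lower.

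The replicate number as a block gave 5 genes higher and 7 lower, of which 5 were among the 16, and 3 lists higher. Deviations of same-numbered samples had correlations of 0.0806, 0.0198 and -0.0604, and control replicate 2 correlated best with knockout replicate 4 (0.138), so the numbers are not taken to pair the samples. Under the block Hmox1 was at -0.24, and list directions turned for the tricarboxylic acid cycle (adjusted p 0.365), antioxidant genes (0.963), cholesterol synthesis (0.922) and Kupffer cell markers (0.365).

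In all, 20 directions of genes and 47 of lists turned, with 0 past the threshold in either setting. For genes these were log2 fold changes of Hmox1 with voom (-0.0238), knockout samples numbered 85 (-0.25) and thinned libraries (-0.0014), of Fech (-0.0247), Tfrc (-0.16), Fgf21 (-0.93) and Afp (-0.11) with samples numbered 82, of Cdkn1a (0.42) and Clpx (0.0062) without knockout replicates 1 and 2, and of Ftl1 (0.0037) without the length trend.

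For lists, given by adjusted p, these were fetal liver genes (0.880) and endothelial markers (0.995) with at least 50 counts. With samples numbered 82 they were cell cycle, p53 targets, periportal genes and stellate cell genes (0.963 each), fatty acid synthesis (0.899), Ppara targets (0.0890), glucose metabolism (0.507), secreted proteins (0.838), cholangiocyte (0.900), lymphocyte (0.649), endothelial (0.171) and erythroid markers (0.712). With knockout samples numbered 85 they were the tricarboxylic acid cycle and Kupffer cell markers (0.403 each) and cholesterol synthesis (0.826). Without knockout replicates 1 and 2 they were antioxidant genes (0.493), secreted proteins (0.931) and endothelial markers (0.777), and without the length trend antioxidant genes (0.891).

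Leaving out each library in turn gave 2 to 11 genes higher and 6 to 19 lower, and 1 to 3 lists higher and 3 to 10 lower. Log2 fold changes ran from -0.0441 to 0.0596 for Fech, -0.17 to 0.14 for Hmox1, -0.81 to 0.18 for Cdkn1a and -0.21 to 1.35 for Fgf21. Adjusted p ran from 0.0172 to 0.883 for cell cycle, 0.00475 to 0.924 for acute-phase genes, 0.0179 to 0.845 for lymphocyte markers, 0.189 to 0.959 for immediate early genes, 0.228 to 0.990 for secreted proteins, 0.590 to 0.982 for endothelial markers, 0.151 to 0.930 for erythroid markers, 0.329 to 0.928 for glucose metabolism, 0.0750 to 0.634 for Kupffer cell markers, 0.291 to 0.932 for antioxidant genes, 0.0268 to 0.966 for Ppara targets, 0.420 to 0.975 for fetal liver genes and 0.0974 to 0.993 for the tricarboxylic acid cycle.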

Other observations

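Tests chosen only after the result was seen were the counts of genes near the deleted loci and of pairs off their chromosomes, the pair statistic itself, the check of Xist, the clock comparison by genotype, and the 9-gene test of clock phase, and the fits without knockout replicates 1 and 2 or without the length trend, the clock difference without that trend, and the pairs off chromosomes 14 and 19 in other splits and with both reductions were also added after seeing the data.

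Clock genes set knockout replicates 1 and 2 apart from the other 6 livers. The output genes Dbp, Per3, Nr1d1, Nr1d2 and Tef were higher in both than in each of the others, and Arntl, Npas2, Cry1 and Nfil3 were lower. Per3 was at 38.0 and 46.0 CPM against 2.36 to 4.56 CPM, and Npas2 at 1.20 and 0.598 CPM against 4.88 to 9.67 CPM. Relative to control, the mean log2 difference of the 5 output genes was 2.90 in these samples and that of the 4 others -1.92.

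The knockout genotype alone is argued against, because the 3 other knockout samples differed from control by -0.26 in the output genes, far from 2.90 and in the other direction. So is a trend with gene length in the libraries, which was positive in these samples (0.169 and 0.217) as in knockout replicate 5 (0.213), since the difference was 2.86 with that trend removed. Whether other broad differences in library quality or content play a part cannot be told from these values. The mean absolute log2 difference of the clock list from the other knockout samples was 1.99. Random lists matched for expression had a median of 0.178, which puts it at percentile 100. The list was fixed beforehand but picked here because it stood apart, so the percentile alone does not decide. Genes of the list also moved both ways. Dbp was at 69.3 and 54.4 CPM against 1.23 to 2.93 CPM in the other livers, and Npas2 at 1.20 and 0.598 CPM against 4.88 to 9.67 CPM. These genes were chosen after their values were seen, so they do not decide either. Tissue taken at another phase of the daily cycle may explain the pattern but was not tested independently, since the 9 of 9 genes in the direction of such a shift were chosen after their values were seen, and Per1, another clock gene, did not stand apart (3.18 and 5.61 against 1.82 to 5.41 CPM). The collection time is not stated in the labels, and an effect of genotype on clock timing in some animals was not tested.

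Genes with small p lay close together on several chromosomes. Of the 100 genes with the smallest p, 6 lay between 50 and 55 Mb on chromosome 14 (Arhgef40, Cebpe, Gm26782, Haus4, Mir686 and Psmb5) and 6 between 135 and 140 Mb on chromosome 6 (Dera, Emp1, Erp27, Hist4h4, Pik3c2g and Rerg). A further 5 lay between 60 and 65 Mb on chromosome 4 (Alad, Gm12909, Mup2, Mup5 and Mup9) and 4 between 20 and 25 Mb on chromosome 17 (Abca3, Atp6v0c, D930048G16Rik and Meiob). These windows were named after they were seen. In all, 96 pairs of the 100 genes lay within 5 Mb of each other, against a median of 28 in random lists, whose central 95% reached 42. This statistic replaced an earlier one that had failed on simulated data.

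Reads shared by overlapping genes and families of neighbouring genes account for part of the excess and not for all of it: 77 pairs against a median of 27 were left with 1 gene kept per set of overlapping genes (permutation p = 1e-04), 69 against 27 with 1 kept per family (permutation p = 1e-04), where 1e-04 is the smallest p the 10000 permutations can give, and 51 against 26 with both reductions (permutation p = 8e-04). DNA linked to the targeted loci may contribute, since 12 of the 100 genes, the deleted genes aside, lay within 20 Mb of Slc25a37 or Slc25a28 against 3.35 expected (exact hypergeometric p = 0.000126, with the central 95% of random lists reaching 7), 8 near Slc25a37 (1.66 expected) and 4 near Slc25a28 (1.68 expected, p = 0.0886). The hypergeometric p treats genes as independent draws, although Mir686 lies inside Psmb5. The count near the loci was not repeated over other splits or with overlapping genes reduced. DNA linked to the targeted loci does not reach the pairs off chromosomes 14 and 19, which numbered 84 against a median of 29 in random lists (permutation p = 1e-04), and 51 against 28 with both reductions (permutation p = 0.0012). That neighbouring genes vary together between any samples stays open for all of these pairs, since 5 of the 56 splits gave at least 96 pairs and 7 gave at least 84 off chromosomes 14 and 19, the highest other being 149 in both cases, for control replicate 3 with knockout replicates 4 and 5. Strain differences at other loci were not tested.

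Higher expression of female-biased liver genes in knockout is argued against as a matter of the sex of the samples, since Xist, which male liver lacks, was at 517 CPM or more in every library. The samples with shifted clock genes are not needed for the higher scores. Knockout replicates 3 to 5 scored 0.791, 0.492 and 0.385, against -0.398 or less in the controls. Nor is the number series, since knockout replicates 4 and 5 and all controls are numbered 82. Camera also called the list without the samples with shifted clock genes (adjusted p = 2.62e-07) and among the samples numbered 82 (0.000524). These calls decide little alone, since 50 of 56 splits gave at least 6 called lists. The 9 members off chromosomes 5, 14 and 19 were also higher (camera p = 0.000579, and 0.0309 with an estimated correlation), which argues against those chromosomes as the whole cause. Whether the 9 members include neighbours on other chromosomes was not examined. Over 21 alternatives the list was called in 20, with camera or fry adjusted p from 1.52e-09 to 0.118, the exception being camera with an estimated correlation. A response of these hormone-controlled genes to loss of the mitoferrins remains a hypothesis, with stage of the estrous cycle and other animal differences untested.

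The count of genes was set against other splits of the 8 samples into 3 and 5. The 16 genes include the deleted Slc25a28, and Cebpe, Psmb5 and Mir686 near Slc25a37, so their number does not exclude chance for the other genes. Of 56 splits 2 gave at least 16 genes, a share under 0.05. These were the real one and the split that parts knockout replicates 1, 2 and 5 from the rest, which gave 19. Those 3 samples also had the highest scores on the leading principal component, at 30.5, 29.5 and 21.3. They alone had a positive correlation of gene length with the deviation of log2 CPM from the mean of the 8 libraries. It was 0.169, 0.217 and 0.213, against -0.261 to -0.0414 in the other libraries, so this split also follows a trait of the libraries. With the length trend removed 7 genes were higher and 10 lower, with all 16 among them. The split that follows the number series, with knockout replicates 1 to 3 apart, gave 1 gene. For the lists 50 of 56 splits gave at least 6, the highest other being 14, so chance is not excluded for their number.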
